A study of Ovis aries with 16 samples.

How the data were processed

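Total RNA from the hypothalamus of 16 fetal sheep, 500 ng per array with RNA integrity numbers of 7.4 to 8.4 per the labels, was labeled with Cy3 and hybridized by the authors to a single-color Agilent ovine array (design 019921), 1 fetus per array. Per the file headers, arrays were read with Feature Extraction 10.1.1.1 (protocol GE1-v5_10_Apr08). The deposited scanner files hold, for each of 15744 features, the processed signal as an intensity in arbitrary units, after the authors' background subtraction and spatial detrending, together with spot flags of other kinds. The deposited value table of the series holds log2 values. Compared with the scanner files, that table was found to be the log2 processed signal minus the median of all features on the array. No statistical test is stated in the labels, so the tests used here are defaults for such data.

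Of the 15744 features 15208 were not controls. They represent 15008 distinct probes, 50 of which had 5 spots each, averaged on the log2 scale. Spots marked by the scanner software as non-uniform or population outliers were set to missing (2 to 36 per array), which touched 83 of the tested probes, and at most 1 probe per array was saturated. Each array's log2 signal was scaled by subtracting its 75th percentile. Probes were tested where the software called them well above background on at least 4 of the 16 arrays, which kept 12937 and left out 2071. Median local background was 56.5 to 65 units and 11596 to 12969 probes per array were well above it. The number of arrays limits precision, and no interval for depth applies to such data.

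Gene names came from the annotation in the files, matched to a table of sheep genes made for assembly ARS-UI_Ramb_v3.0, which was used for names alone. Of 15008 probes 719 matched by accession, 511 by symbol, 125 by gene identifier and 20 by synonym, 273 kept the name given in the files, and 13352 remained unnamed, mostly expressed sequence tags. A further 8 probes whose name and accession pointed to different genes were left unnamed. In all 1648 probes carried 1020 names. Genes with several probes were represented in lists by the brightest probe.

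A linear model with the 4 groups was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and 2-sided tests. There were 8 comparisons: BCO against control, estradiol+BCO against estradiol, estradiol against control, estradiol+BCO against BCO, estradiol+BCO against control, each treatment averaged over the other, and the interaction. Probes passed at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the probes of each comparison. From genes fixed in advance, 31 lists of pathways and of cell types were drawn up, 18 of which had at least 5 measured genes and were tested, while 13 were too small. They were tested with camera at its preset correlation of 0.01, and called at an adjusted p under 0.05 over the 18 lists. Camera with an estimated correlation and fry, whose p-value asks whether the genes of a list move on balance one way, were run beside it. At the estimated correlation 0 lists were called in any of the 8 comparisons. By fry 1 was called for BCO against control, 1 for estradiol+BCO against estradiol and 2 for BCO averaged over estradiol, and 0 in the other 5 comparisons. In the called lists the median, the mean and the test had the same sign.

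Named genes were chosen by a rule: up to the 10 largest rises and 10 largest falls past the threshold, and, where fewer than 5 named probes passed, the 5 higher and 5 lower genes with the lowest p; up to 4 members with the lowest p of each list that was called or had at least 2 members past a threshold adjusted over the list alone; and a panel of 16 genes. One gene that this rule chose in estradiol against control is not reported here. Of the panel 11 had a tested probe; NR4A1, HSPA1A, CRH and AVP carried no probe under those names, and SLC2A1 appeared only under an older name, GLUT-1 (log2 fold change 0.26 for BCO against control, adjusted p = 0.706). Unnamed probes past the threshold were chosen after their values were seen. Groups, comparisons, lists, the panel, this rule and the alternatives were fixed before the data were examined. Where a gene was not well above background on any array of one group, the fold is given as a lower bound, computed against the larger of its own signal and the lowest signal that was well above background on each array of that group. That floor is set by the dimmest such probe of the array, so the bound depends on it and on the background correction.

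The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 16 arrays, slide as a block, each slide alone, the replicate number as a block, the log2 value table of the series, trended and robust moderation, the groups compared alone, the mean of all probes of a gene, the list tests above, and leaving out each array in turn. The pipeline was tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold among 12854. For BCO against control it recovered 69 of 100 probes changed 2-fold and 91 of 100 changed 4-fold, with 12 false calls. For estradiol+BCO against estradiol it recovered 70 and 90 of 100, for estradiol against control 66 and 93, for estradiol+BCO against BCO 65 and 92 and for estradiol+BCO against control 67 and 92. The averaged effects gave 81 and 98 for BCO and 84 and 95 for estradiol, and the interaction 43 and 77. With nothing changed it made 0 calls in each comparison. In a simulation over 900 genes, 17 of 18 lists shifted by 0.5 on the log2 scale were recovered and 0 in the wrong direction. Both simulations drew each probe independently around its own mean and spread, with no slide difference and no genes moving together. They therefore cannot show how often calls are false in the real arrays, where 858 probes differed between the slides.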

Results

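Hypothalamic RNA from 16 fetal sheep was hybridized to a single-color ovine oligonucleotide array to ask how a short interruption of cerebral blood flow, and prior treatment with estradiol, altered transcript abundance in the late-gestation fetal brain. Brachiocephalic occlusion (BCO) lowers flow in the artery that feeds the head of the fetus. There were 4 groups of 4 fetuses: control fetuses with a sham occlusion, fetuses given BCO for 10 min, fetuses given estradiol (250 ug per day for 5 days) with a sham occlusion, and fetuses given both estradiol and BCO. Fetuses were studied at 124 to 128 days of gestation (term is 147 days), and tissue was taken 1 h after the start of the occlusion or sham period. The 75th percentile of the signal lay between 2021 and 2904 units, and 77.27% to 86.41% of the 15008 distinct probes on an array lay well above background. Arrays sat on 2 slides, each with 2 arrays of every group. In a test of slide with the 4 groups in the model, 858 probes differed between the slides (759 higher and 99 lower on slide 2). Each comparison below therefore carries its values within each slide. Group values are log2 signal minus the 75th percentile of the array, and 12937 probes were tested, 1397 of which carried the name of 1 of 903 genes. The number of arrays limits the precision of every value.

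The comparison of BCO with control asked what occlusion did without added estradiol. Messenger RNAs of hypothalamic neuropeptides were lower after BCO: the list of 14 measured neuropeptide genes had 13 members with lower and 1 with higher mean signal. With a median log2 fold change of -1.63 it fell as a group by camera (adjusted p = 1.27e-10). The neuropeptide list had an adjusted p = 0.0593 with an estimated correlation, and its adjusted p ran from 2.69e-13 to 0.0593 over 13 alternative settings. GHRH, the releasing hormone for growth hormone, was at -2.23 ± 1.36 (SD, n = 4) in control and was not well above background on any BCO array. Against the floor used here it was at least 33.0-fold lower after BCO. With normexp background correction, whose offset compresses dim signals, its log2 fold change was -3.13, a smaller fall than that bound. AGRP, an appetite-stimulating peptide of the arcuate nucleus, went from -1.04 ± 0.64 to -5.84 ± 0.37 (SD, n = 4 each), and galanin (GAL) from -0.44 ± 0.46 to -3.26 ± 0.66. Counted with a threshold adjusted over the list alone, 9 of the 14 neuropeptide genes were lower and 0 were higher, whereas 0 passed over all probes. These 9 were GHRH, AGRP, GAL, gastrin-releasing peptide (GRP, -1.18 ± 0.31, SE), somatostatin (SST, -1.32 ± 0.41) and oxytocin (OXT, -2.71 ± 0.90), together with the RFamide peptide precursor NPVF (-2.89 ± 0.95), POMC, the precursor of ACTH and beta-endorphin (-1.55 ± 0.51), and neurokinin B (TAC3, -1.06 ± 0.42). For GHRH, AGRP, GAL and POMC the 4 BCO arrays all lay below the 4 control arrays. The list median was -1.37 within slide 1 and -2.05 within slide 2. With GHRH set at its bound the median was again -1.63. PMCH, the precursor of melanin-concentrating hormone, differed by 0.38 and TAC1, the substance P precursor, by -0.06. Of 3 measured transcription factors of hypothalamic nuclei, NR5A1 (ventromedial nucleus) differed by -2.18 ± 0.67 (SE; adjusted p = 0.489), ISL1 (arcuate neurons) by -1.24 ± 0.53 (adjusted p = 0.649) and ARNT2 by -0.05 ± 0.14. NEUROD1, a marker of thalamus and telencephalon, differed by -0.72 ± 0.35. Among cell-type lists that were not called, the pituitary list had 8 of 9 members lower (median -0.67, adjusted p = 0.103). The microglia and leukocyte list had 7 of 7 lower (median -0.30, adjusted p = 0.0582, and -0.04 and -0.43 within slides), and the endothelial and mural list 7 of 7 higher (median 0.20, adjusted p = 0.146).

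Genes of the hypothalamus-pituitary-adrenal axis did not shift as a group after BCO (10 genes, median -0.06, adjusted p = 0.306). With a threshold adjusted over the list alone 2 of them were lower, POMC and the binding protein of corticotropin-releasing hormone, CRHBP (-1.02 ± 0.28, SE). The estrogen receptor ESR1 differed by -1.53 ± 0.41 (adjusted p = 0.468), with the 4 BCO arrays all below the 4 control arrays, and by -1.93 and -1.14 within slides 1 and 2. Of the 8 cell-cycle genes measured, 7 were higher and the list rose as a group by camera (median 0.26, adjusted p = 0.0105), led by CDK1, the mitotic kinase (0.55 ± 0.25), AURKA (0.30 ± 0.16), CDK2 (0.21 ± 0.11) and CCND2 (0.36 ± 0.23). The cell-cycle list had an adjusted p = 0.405 with an estimated correlation, and its adjusted p ran from 0.00102 to 0.667 over 13 alternative settings. Of the 8, 0 passed a threshold adjusted over the list alone, and the medians within slides were 0.35 and 0.08. The call was lost without control replicate 2 (adjusted p = 0.114), BCO replicate 1 (0.107) or BCO replicate 2 (0.0579). The named genes with the lowest p on the higher side were AGGF1, an angiogenic factor (0.45 ± 0.09), SELP, an adhesion molecule of activated endothelium and platelets (1.91 ± 0.41), the prion protein gene PRNP (0.38 ± 0.09), the KIT ligand KITLG (1.89 ± 0.50) and the metabotropic glutamate receptor listed as MGLUR1 (0.61 ± 0.18). The SELP, PRNP and MGLUR1 values came from a dimmer probe of each gene. SELP was 0.72 within slide 1, 3.09 within slide 2 and 0.82 with normexp background correction. On the lower side stood GAL, GHRH and AGRP with the dimmer probes of the axon guidance gene SLIT2 and the gluconeogenic enzyme gene PCK1. Neither of these probes was well above background on any BCO array (at least 1.12-fold and 1.56-fold lower; -0.15 and -0.40 on the log2 scale with normexp background correction), and the brighter probes gave -0.47 and -0.40. Among activity-dependent genes FOS was at -0.02 ± 0.32, with a sign that turned in 8 of 29 alternative fits, JUNB at 0.74 ± 0.41 and EGR1 at -0.11 ± 0.14, whose dimmer probe gave 0.60. The vascular growth factor VEGFA differed by 0.38 ± 0.21 and the prostaglandin synthase PTGS2 by 0.17 ± 0.59. By limma, 0 of 12937 probes passed in this comparison (smallest adjusted p = 0.466), with 928 at an unadjusted p under 0.05 (7.17%, where 5% are expected by chance). With slide as a block these counts were 0 and 1083. Within slide 2 there were 14 (2 higher and 12 lower, with NPY at -2.54 and AGRP at -5.42 among them). With the groups compared alone in the fit 3 were lower, and without BCO replicate 2 there were 6. Single arrays stood apart from the other 3 of their group for SST (BCO replicate 4), NPVF (BCO replicate 1), TAC3 (estradiol replicate 2) and MGLUR1 (control replicate 2). The vasopressin receptor AVPR1B, with estradiol replicate 1 apart, differed by 0.81 ± 0.55 between BCO and control.

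**Figure D1:**
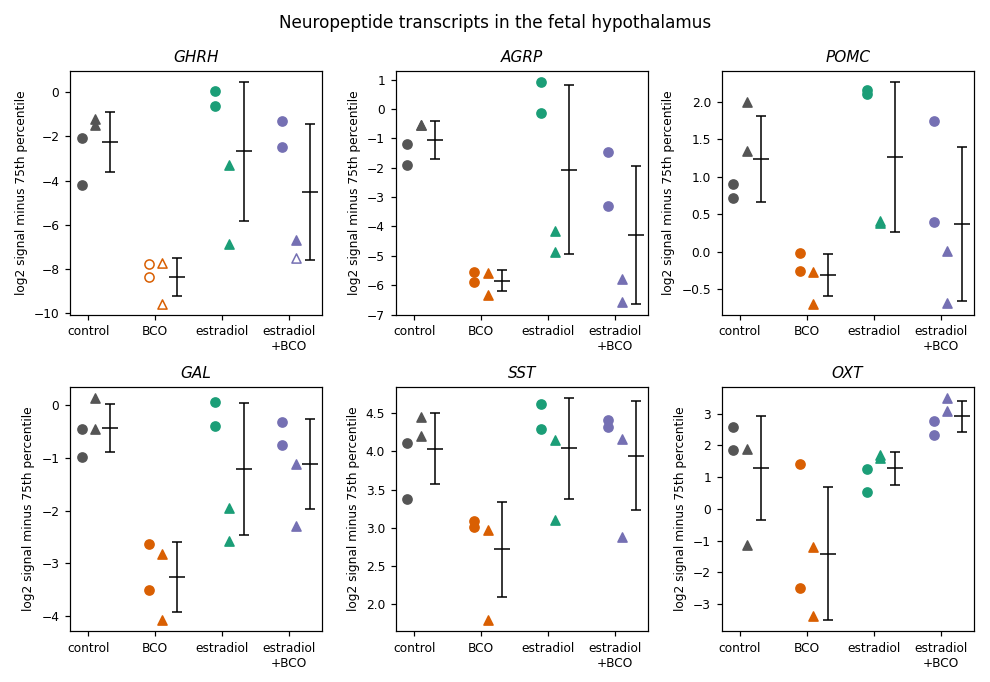
Log2 signal minus the 75th percentile of the array (vertical axis) for GHRH, AGRP, POMC, GAL, SST and OXT in control, BCO, estradiol and estradiol+BCO fetuses, with circles for arrays of slide 1, triangles for arrays of slide 2, open markers for values not well above background, and bars for mean ± SD (n = 4). The BCO arrays of GHRH (-9.57 to -7.73), AGRP (-6.34 to -5.53), POMC (-0.69 to -0.01) and GAL (-4.08 to -2.63) all lie below the control arrays of the same gene.

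The comparison of estradiol+BCO with estradiol asked what occlusion did in estradiol-treated fetuses. Inflammation genes were higher after BCO in these fetuses: 17 of the 22 measured had higher mean signal, and the list rose as a group by camera (median 0.32, adjusted p = 0.00672), with medians of 0.22 and 0.23 within slides. The inflammation list had an adjusted p = 0.531 with an estimated correlation, and its adjusted p ran from 0.00566 to 0.531 over 13 alternative settings. Its leading members were the cytokine gene TNF (0.86 ± 0.30, SE), with the 4 arrays of one group all above the 4 of the other and a value of 0.31 with normexp background correction, interleukin 1 alpha (IL1A, 0.83 ± 0.52), the transcription factor CEBPB (0.49 ± 0.29) and the pattern receptor TLR4 (0.32 ± 0.19, and 0.02 with normexp background correction). Genes of the adrenal axis fell as a group (9 of 10 lower, median -0.37, adjusted p = 0.0314), with -0.30 and -0.27 within slides. The axis list had an adjusted p = 0.231 with an estimated correlation and 0.0072 by fry, and its adjusted p ran from 0.0072 to 0.231 over 13 alternative settings. Examples were the cholesterol transport gene STAR (-0.76 ± 0.30), the peptide-processing enzyme CPE (-0.26 ± 0.11), POMC (-0.90 ± 0.51) and HSD11B1, which regenerates active glucocorticoid (-0.42 ± 0.30). All 5 genes of the fibroblast and meninges list were lower and the list fell as a group (median -0.53, adjusted p = 0.00672), with medians of -0.84 and -0.22 within slides. The fibroblast list had an adjusted p = 0.531 with an estimated correlation, and its adjusted p ran from 0.00574 to 0.531 over 12 alternative settings. The collagen gene COL1A2 (-0.86 ± 0.26) passed a threshold adjusted over the list alone; COL3A1 (-0.53 ± 0.24), DCN (-0.41 ± 0.27) and FBLN1 (-0.29 ± 0.19) did not. The counts that passed a threshold adjusted over the list alone were 0 of 22 inflammation genes, 0 of 10 axis genes and 1 of 5 fibroblast genes. The glutamate and GABA list was not called (adjusted p = 0.161), though 2 of its 7 members were lower with a threshold adjusted over the list alone. These were the AMPA receptor subunit GRIA4 (-0.43 ± 0.13) and glutamate dehydrogenase GLUD1 (-0.43 ± 0.15), while GRIN1 was at -0.34 ± 0.20 and GRM5 at 0.17 ± 0.18. The neuropeptide list was not called in these fetuses: 9 of 14 genes were lower, with a median of -0.11 (adjusted p = 0.419) and -0.25 and -0.31 within slides. The mean of its members GHRH, AGRP, POMC, NPY and GAL differed by -1.26, while that of OXT, GNRH1 and NPVF went from -1.83 to -1.05.

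In the same comparison 1 of 12937 probes passed by limma, with 1000 probes at an unadjusted p under 0.05. It was A_70_P055401, an expressed sequence tag with no gene name, chosen after its values were seen. It fell by 0.96 ± 0.13 on the log2 scale (SE; adjusted p = 0.0275), from -1.19 ± 0.17 to -2.16 ± 0.14 (SD, n = 4 each), with -0.92 and -1.01 within slides and an adjusted p of 0.0129 with slide as a block. It passed in 12 of 28 alternative fits (adjusted p = 0.0129 to 0.989), and its fold change ranged from -1.03 to -0.91 in them. In fits that left out 1 array the probe passed in 6 of 16. The number of probes was 0 without control replicates 3 or 4, BCO replicates 2 or 3, estradiol+BCO replicates 1 or 4, or estradiol replicates 1, 2 or 3, and without estradiol+BCO replicate 3 another unnamed probe passed in its place (A_70_P028551, 1.04). Without estradiol+BCO replicate 1 the 3 lists were lost as well (adjusted p = 0.156 for inflammation, 0.118 for the adrenal axis and 0.118 for fibroblasts). The axis list was also lost without estradiol+BCO replicate 4 (0.0619), estradiol replicate 1 (0.0715) or estradiol replicate 3 (0.0645). Named genes with the lowest p, of which 0 passed, were higher for pyridoxal kinase PDXK (0.59 ± 0.12), the glucose transporter SLC2A3 (0.56 ± 0.17), the peptide transporter SLC15A1 (1.46 ± 0.45, but -0.04 with normexp background correction), CD40 (0.83 ± 0.24, a dimmer probe) and the interferon receptor IFNAR1 (0.34 ± 0.10). They were lower for the Hedgehog receptor PTCH1 (-0.74 ± 0.18), the VEGF receptor KDR (-0.76 ± 0.19, a dimmer probe), AGGF1 (-0.38 ± 0.10, a dimmer probe), FTO (-0.50 ± 0.13) and YEATS4 (-0.40 ± 0.11). The adjusted p of these genes ran from 0.172 for PDXK to 0.427. Panel genes ran from -0.90 for POMC to 1.64 for OXT, with FOS at 0.59 ± 0.32. Single arrays stood apart for STAR (estradiol replicate 4), COL3A1 (estradiol replicate 2), GRM5 (estradiol replicate 3) and PTCH1 (control replicate 1). The same held for SLC15A1 (BCO replicate 4), DCN (BCO replicate 3 and control replicate 2) and FBLN1 (control replicate 2).

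The comparison of estradiol with control asked what 5 days of estradiol did in sham-occluded fetuses. By limma 0 of 12937 probes passed (smallest adjusted p = 1, 424 probes at an unadjusted p under 0.05, and 0 and 519 with slide as a block), and 0 of 18 lists were called by camera at the preset correlation, with the correlation estimated, or by fry. The estrogen receptors ESR1 (-0.16 ± 0.41, SE) and ESR2 (-0.11 ± 0.32) and the progesterone receptor PGR (-0.01 ± 0.39) differed by less than their errors, and the 13 genes of the estrogen signalling list had a median of -0.01 (adjusted p = 0.781). Named genes with the lowest p were higher for AGGF1 (0.44 ± 0.09), the proton pump subunit ATP6V1B2 (0.45 ± 0.13), the integrin ITGA4 (0.58 ± 0.19), the astrocyte filament gene GFAP (0.75 ± 0.26) and the adaptor NCK1 (0.32 ± 0.11). They were lower for the water channel AQP3 (-1.04 ± 0.25), the orexin receptor HCRTR1 (-0.90 ± 0.22), the receptor kinase KIT (-0.69 ± 0.26, but 0.06 with normexp background correction) and RPSA (-0.45 ± 0.17). For AGGF1, NCK1, AQP3 and HCRTR1 the 4 arrays of one group lay all on one side of the other 4. The ATP6V1B2, ITGA4, GFAP and AQP3 values came from a dimmer probe, and the brighter ITGA4 probe gave -0.02. Within slides AGGF1 was 0.39 and 0.49, GFAP 0.81 and 0.69, AQP3 -0.72 and -1.35 (-0.16 over both slides with normexp background correction), and HCRTR1 -0.96 and -0.84. PTGS2 differed by 1.12 ± 0.59 and FOS by 0.49 ± 0.32. POMC was 1.32 within slide 1 and -1.27 within slide 2, and OXT -1.30 and 1.28. Lists numbered 3 higher within slide 1 alone and 1 lower within slide 2 alone, where 1 probe also passed. Single arrays stood apart for ATP6V1B2 (estradiol+BCO replicate 2), ITGA4 (estradiol replicate 3 and estradiol+BCO replicate 4), KIT (estradiol+BCO replicate 3) and ESR2 (control replicate 2 and estradiol replicate 1).

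The comparison of estradiol+BCO with BCO asked how occluded fetuses differed with estradiol treatment. Neuropeptide transcripts were higher with estradiol: 12 of the 14 genes had higher mean signal, and the list rose as a group by camera (median 1.09, adjusted p = 8.06e-05). The 4 BCO arrays are those in which the list was lower than in control, so this result partly restates that fall. Against control 12 of the 14 genes were lower in estradiol+BCO fetuses, and estradiol against control called 0 lists. Dissection was not measured, which limits this comparison too. The neuropeptide list had an adjusted p = 0.308 with an estimated correlation, and its adjusted p ran from 2.27e-08 to 0.308 over 13 alternative settings. OXT stood at -1.41 ± 2.09 in BCO and 2.92 ± 0.48 in estradiol+BCO fetuses (SD, n = 4 each), a log2 difference of 4.33 ± 0.90 (SE; adjusted p = 0.149) with the 4 arrays of one group all above the 4 of the other. With a threshold adjusted over the list alone 4 genes were higher, OXT, GAL (2.14 ± 0.56), GRP (0.94 ± 0.31) and SST (1.23 ± 0.41), and 0 were lower. The list median was 1.27 within slide 1 and 0.55 within slide 2, where the call was lost (adjusted p = 0.13). On slide 2 the mean of GHRH, AGRP, POMC, NPY and GAL was -3.46 and -3.07 in estradiol+BCO and -3.41 and -4.16 in BCO fetuses. On slide 1 it was -1.22 and 0.03 in estradiol+BCO and -3.52 and -3.20 in BCO fetuses. The transcription factor NR5A1 of the ventromedial nucleus differed by 1.95 ± 0.67 (adjusted p = 0.365), ISL1 by 0.59 ± 0.53 and ARNT2 by -0.10 ± 0.14. Of 7 microglia and leukocyte genes 6 were higher and the list rose (median 0.25, adjusted p = 0.0187), with medians of 0.34 and 0.38 within slides. The microglia list had an adjusted p = 0.308 with an estimated correlation, and its adjusted p ran from 0.0106 to 0.311 over 13 alternative settings. All 7 genes had been lower in BCO than in control, and against control 4 of 7 were higher in estradiol+BCO fetuses (adjusted p = 0.751). Within it the Fc receptor chain FCER1G (0.60 ± 0.17) and the leukocyte integrin ITGB2 (0.56 ± 0.17) passed a threshold adjusted over the list alone, 2 genes in all, and CD14 was at 0.37 ± 0.18 and ITGAM at 0.16 ± 0.21. Of 22 inflammation genes 17 were higher and the list rose (median 0.39, adjusted p = 0.00944), but the median was 0.58 within slide 1 and -0.06 within slide 2. The inflammation list had an adjusted p = 0.308 with an estimated correlation, and its adjusted p ran from 5.65e-07 to 0.923 over 13 alternative settings. Examples were the interleukin 1 receptor antagonist IL1RN (at least 1.96-fold higher, not well above background on any BCO array), IL1B (0.46 ± 0.18) and IL6 (0.41 ± 0.19), with 0 of 22 past a threshold adjusted over the list alone. All 7 glutamate and GABA genes were lower and the list fell (median -0.30, adjusted p = 0.0169), with -0.27 and -0.27 within slides. The glutamate list had an adjusted p = 0.308 with an estimated correlation, and its adjusted p ran from 0.00475 to 0.308 over 13 alternative settings. Its NMDA receptor subunit GRIN1 (-0.72 ± 0.20) passed a threshold adjusted over the list alone, as 1 gene of 7, while GRIA4 (-0.32 ± 0.13), GLUD1 (-0.35 ± 0.15) and GRIA3 (-0.30 ± 0.16) did not.

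Beyond these lists, FOS was 2.14-fold higher (SE 0.32 on the log2 scale) with estradiol among occluded fetuses, as 1 of 10 immediate early genes past a threshold adjusted over the list alone, and that list was not called (adjusted p = 0.6). The epidermal growth factor receptor ligand AREG (1.69 ± 0.33), the troponin gene TNNC2 (0.56 ± 0.15) and FCER1G, OXT and GAL had the lowest p among higher named genes. PRNP (-0.51 ± 0.09), the lamin gene LMNB1 (-0.49 ± 0.10), KDR (-0.79 ± 0.18), the fatty acid oxidation gene CPT1A (-0.62 ± 0.14) and AGGF1 (-0.38 ± 0.10) had the lowest among lower ones. The TNNC2, PRNP, KDR, CPT1A and AGGF1 values came from a dimmer probe, and the mean over all PRNP probes was -0.09. By limma 0 of 12937 probes passed (smallest adjusted p = 0.149, 1222 probes at an unadjusted p under 0.05, and 0 and 1463 with slide as a block). Within slide 2, 13 probes were higher. Without BCO replicate 1 there were 5, among them both OXT probes (5.21 and 5.28) and PRNP (-0.58), with 3 without BCO replicate 2 and 1 without BCO replicate 4. The inflammation call was lost without BCO replicate 2 (adjusted p = 0.118) or estradiol+BCO replicate 1 (0.0845). Lost too were the glutamate call without BCO replicate 2 (0.103) or estradiol+BCO replicate 3 (0.115), and the microglia call without BCO replicate 4 (0.129), estradiol+BCO replicate 1 (0.0605) or estradiol+BCO replicate 4 (0.0512). Single arrays stood apart for SST (BCO replicate 4 and estradiol+BCO replicate 3), the dimmer probe of FCER1G (estradiol+BCO replicate 1) and ITGB2 (estradiol replicate 3).

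The comparison of estradiol+BCO with control set both treatments against neither. Inflammation genes were higher: 16 of 22 had higher mean signal, and the list rose as a group by camera (median 0.39, adjusted p = 1.09e-05). The inflammation list had an adjusted p = 0.178 with an estimated correlation and 0.0941 by fry, and its adjusted p ran from 4.93e-09 to 0.178 over 13 alternative settings. SELP was at -5.82 ± 0.64 in control and -4.19 ± 0.36 in estradiol+BCO fetuses (SD, n = 4 each), a log2 difference of 1.63 ± 0.47 (SE) that was 0.79 with normexp background correction, and the NF-kappa B inhibitor NFKBIA, itself an NF-kappa B target, was at 0.43 ± 0.18 and 1.78 ± 0.73. IL1A differed by 1.56 ± 0.52 (SE) and the adhesion molecule ICAM1 by 2.61 ± 0.93. For SELP, NFKBIA, IL1A and ICAM1 the 4 estradiol+BCO arrays all lay above the 4 control arrays, though 0 of 22 genes passed a threshold adjusted over the list alone. The list median was 0.45 within slide 1 and 0.22 within slide 2, where the call was lost (adjusted p = 0.083), and the microglia and leukocyte list had a median of 0.18 (adjusted p = 0.751). All 5 fibroblast and meninges genes had lower mean signal, but that list was not called (median -0.40, adjusted p = 0.0686), and the choroid plexus gene TTR differed by -2.15 ± 1.12. FOS (1.08 ± 0.32) was the 1 gene of 10 in the immediate early list past a threshold adjusted over the list alone, JUNB was at 1.01 ± 0.41, and the list had an adjusted p of 0.0686. Of 14 neuropeptide genes 12 had lower mean signal, but the list was not called (median -0.52, adjusted p = 0.0863, and 0.22 and -0.90 within slides). OXT, 1 of the 2 higher ones, differed by 1.63 ± 0.90, and POMC by -0.87 ± 0.51, with 0.27 within slide 1 and -2.01 within slide 2.

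Other named genes with the lowest p against control were higher for the interferon-regulated transcription factor IRF1 (2.73 ± 0.55), the hypoxia-inducible factor EPAS1 (0.76 ± 0.18, with 0.06 from its dimmer probe and 0.22 with normexp background correction) and PDXK (0.50 ± 0.12). They were lower for AQP3 (-1.36 ± 0.25, and -0.48 with normexp background correction), the netrin gene NTN4 (-0.67 ± 0.18), the Hedgehog signal transducer SMO (-0.47 ± 0.15), the tight junction gene CLDN1 (-0.72 ± 0.23) and FGF10 (-0.76 ± 0.25), of which AQP3, SMO and FGF10 were read from a dimmer probe. By limma 0 of 12937 probes passed (smallest adjusted p = 0.336, that of AQP3, 751 probes at an unadjusted p under 0.05, and 0 and 890 with slide as a block). Within slide 2 alone 3 passed, among them NPY (-3.12) and AGRP (-5.64). The number of lists was 1 in the full fit, 6 without control replicate 2, 3 without estradiol+BCO replicate 1, 2 without estradiol+BCO replicate 3 and 3 without estradiol replicate 2.

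**Figure D2:**
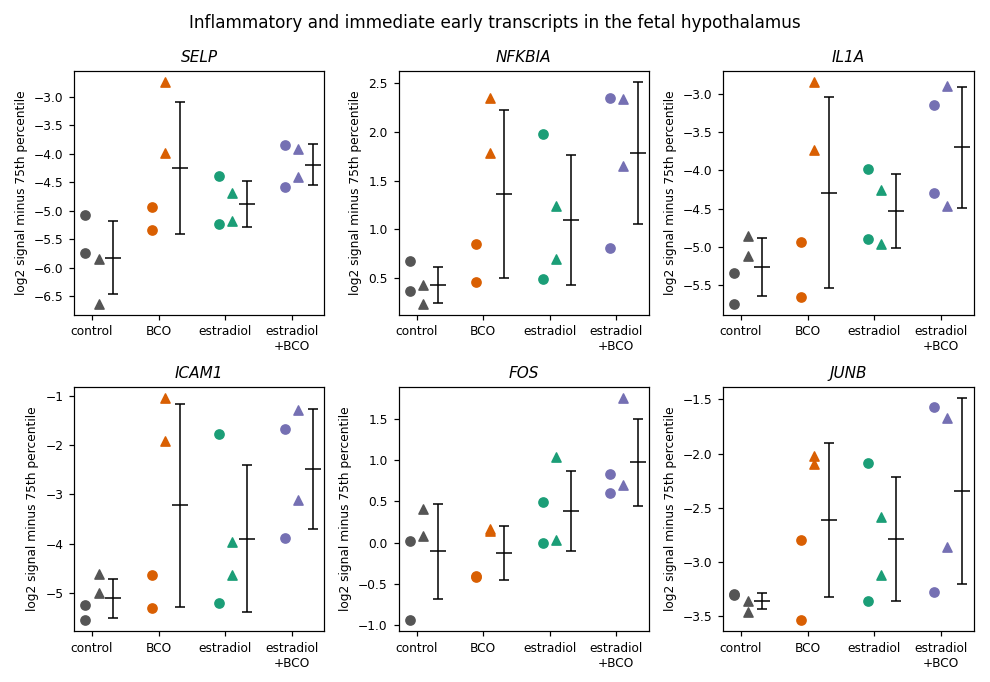
Log2 signal minus the 75th percentile of the array (vertical axis) for SELP, NFKBIA, IL1A, ICAM1, FOS and JUNB in control, BCO, estradiol and estradiol+BCO fetuses, with circles for arrays of slide 1, triangles for arrays of slide 2, open markers for values not well above background, and bars for mean ± SD (n = 4). The estradiol+BCO arrays of NFKBIA (0.80 to 2.34) and FOS (0.60 to 1.75) lie above the control arrays of the same gene (0.24 to 0.67 and -0.94 to 0.41).

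The effect of BCO averaged over estradiol treatment compared 8 occluded with 8 sham fetuses. Neuropeptide genes were lower: 13 of 14 had lower mean signal, and the list fell as a group by camera (median -1.06, adjusted p = 3.96e-07), with medians of -1.01 and -0.99 within slides. The neuropeptide list had an adjusted p = 0.13 with an estimated correlation and 0.023 by fry, and its adjusted p ran from 4.16e-09 to 0.13 over 13 alternative settings. This average joined a median of -1.63 in fetuses without estradiol, where the list was called, and of -0.11 with estradiol, where it was not (adjusted p = 0.419). With a threshold adjusted over the list alone 8 genes were lower, among them AGRP (-3.51 ± 0.87, SE), TAC3 (-1.08 ± 0.29) and GAL (-1.36 ± 0.40). The others were NPY (-1.57 ± 0.55), POMC (-1.22 ± 0.36), the pituitary adenylate cyclase-activating peptide ADCYAP1 (-0.97 ± 0.33), SST (-0.71 ± 0.29), and GHRH, for which no fold is given because it was not well above background on any BCO array. TAC3 was lower than the sham mean on 8 of 8 occluded arrays, and AGRP on 7 of 8. Genes of the adrenal axis also fell (7 of 10 lower, median -0.30, adjusted p = 0.0283), with POMC and CRHBP (-0.67 ± 0.19) past a threshold adjusted over the list alone, 2 in all, and HSD11B1 at -0.46 ± 0.21. The axis list had an adjusted p = 0.13 with an estimated correlation and 0.0171 by fry, and its adjusted p ran from 0.0116 to 0.232 over 13 alternative settings. Cell-cycle genes rose (8 of 8 higher, median 0.16, adjusted p = 0.00534), with AURKA at 0.31 ± 0.11, CDK1 at 0.47 ± 0.18, cyclin A2 (CCNA2) at 0.43 ± 0.18 and TYMS at 0.22 ± 0.12. The cell-cycle list had an adjusted p = 0.342 with an estimated correlation, and its adjusted p ran from 0.00211 to 0.342 over 13 alternative settings. Inflammation genes rose (15 of 22 higher, median 0.24, adjusted p = 0.00804), with SELP at 1.13 ± 0.33, NFKBIA at 0.81 ± 0.31, TNF at 0.58 ± 0.21 and, in the other direction, IL6 at -0.37 ± 0.13. The inflammation list had an adjusted p = 0.332 with an estimated correlation, and its adjusted p ran from 0.00488 to 0.332 over 13 alternative settings. Of the cell-cycle and inflammation genes 0 passed a threshold adjusted over the list alone. Medians within slides were -0.38 and -0.18 for the axis, 0.20 and 0.14 for the cell cycle and 0.11 and 0.20 for inflammation. ESR1 (-0.99 ± 0.29) and the transcription factor GATA3 (1.15 ± 0.36) were 2 of 13 estrogen signalling genes past a threshold adjusted over the list alone, in opposite directions. That list was not called (adjusted p = 0.806). The pituitary list (median -0.92, adjusted p = 0.0679) and the fibroblast and meninges list (5 of 5 lower, median -0.27, adjusted p = 0.0529) were not called. NR5A1 differed by -1.25 ± 0.48, ISL1 by -0.75 ± 0.37 and ARNT2 by -0.06 ± 0.10.

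Among other named genes, PDXK (0.37 ± 0.08), KITLG (1.44 ± 0.35), the T-cell receptor chain CD247 (1.14 ± 0.28) and SLC15A1 (1.22 ± 0.32, and 0.10 with normexp background correction) were on the higher side of the averaged BCO effect. The prohormone convertase listed as PC1 (-0.68 ± 0.17) and EM4C (-1.22 ± 0.32) were on the lower side, with the dimmer probes of SLIT2 and PCK1, whose BCO signals were not well above background, so that no fold is given. PDXK, SLC15A1, PC1 and EM4C lay in their direction on 8 of 8 occluded arrays. By limma 0 of 12937 probes passed (smallest adjusted p = 0.457, 983 probes at an unadjusted p under 0.05, and 0 and 1134 with slide as a block). Without estradiol+BCO replicate 1 the lists went from 4 to 1, with an adjusted p of 0.0547 for inflammation, for the cell cycle and for the axis. The axis call was lost also without control replicate 1 (0.0984), BCO replicate 2 (0.0929) or estradiol replicate 1 (0.0639). Single arrays stood apart for CD247 (BCO replicate 4 and estradiol replicate 4) and PC1 (estradiol+BCO replicate 3).

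The effect of estradiol averaged over occlusion compared 8 treated with 8 untreated fetuses. Inflammation genes were higher (17 of 22) and the list rose as a group by camera (median 0.21, adjusted p = 0.00315), with PTGS2 at 0.91 ± 0.41 (SE), IL1A at 0.66 ± 0.37 and NFKBIA at 0.55 ± 0.31. The inflammation list had an adjusted p = 0.583 with an estimated correlation, and its adjusted p ran from 4.84e-08 to 0.935 over 13 alternative settings. Neuropeptide genes were higher (12 of 14) and that list rose too (median 0.36, adjusted p = 0.00916), with OXT at 2.16 ± 0.63, SST at 0.62 ± 0.29 and GAL at 0.68 ± 0.40. The neuropeptide list had an adjusted p = 0.583 with an estimated correlation, and its adjusted p ran from 8.17e-10 to 0.583 over 13 alternative settings. No fold is given for IL1RN and GHRH, also on the higher side, which were not well above background on any BCO array. Of either list 0 genes passed a threshold adjusted over the list alone. The neuropeptide rise also draws on the BCO arrays in which that list was lower than in control. Both directions turned on slide 2: the inflammation median was 0.35 within slide 1 and -0.01 within slide 2, and the neuropeptide median 0.96 and -0.11. NR5A1 differed by 1.02 ± 0.48 (SE, adjusted p = 0.879 by limma), ISL1 by 0.10 ± 0.37 and ARNT2 by -0.08 ± 0.10. The microglia and leukocyte list was not called (adjusted p = 0.104 by camera). FOS was higher by 0.80 ± 0.23, in that direction on 8 of 8 treated arrays. The astrocyte list was not called (adjusted p = 0.922), but 2 of its 5 genes passed a threshold adjusted over the list alone. These were the water channel AQP4 (0.40 ± 0.12) and the growth factor receptor FGFR3 (-0.33 ± 0.10), in opposite directions, while GFAP was at 0.25 ± 0.19 and the gap junction gene GJA1 at -0.18 ± 0.13. LMNB1 (-0.34 ± 0.07), AQP3 (-0.77 ± 0.18), PRNP (-0.22 ± 0.06) and the glutamate receptor listed as MGLUR3 (-0.59 ± 0.16) were lower, and ATP6V1B2 (0.37 ± 0.09) and CCR10 (0.39 ± 0.11) higher. The AQP3, PRNP, ATP6V1B2 and CCR10 values came from a dimmer probe, and 8 of 8 treated arrays lay in that direction for each of these 6 genes except CCR10 (7 of 8). By limma 0 of 12937 probes passed (smallest adjusted p = 0.74, 722 probes at an unadjusted p under 0.05, and 0 and 893 with slide as a block), with 1 without estradiol replicate 4. The neuropeptide call was lost without estradiol replicate 2 (adjusted p = 0.0894), and the number of lists was 5 without control replicate 4 and 4 without estradiol replicate 4. Single arrays stood apart for MGLUR3 (BCO replicate 2) and GJA1 (estradiol+BCO replicate 4).

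The interaction asked whether the effect of BCO differed between estradiol-treated and untreated fetuses, with positive values for a higher fold change of BCO under estradiol. The neuropeptide list differed: 12 of 14 genes had positive values, with a median of 1.37 (adjusted p = 0.000408 by camera), and medians of 0.90 and 1.75 within slides. The BCO arrays with low neuropeptide signal enter here too, so this result is not independent of the fall in BCO against control. The neuropeptide list had an adjusted p = 0.717 with an estimated correlation, and its adjusted p ran from 6.49e-07 to 0.717 over 13 alternative settings. With a threshold adjusted over the list alone 3 genes passed, OXT (4.35 ± 1.27, SE), GAL (2.92 ± 0.79) and GRP (1.51 ± 0.44), while NPVF was at 3.70 ± 1.34. Of the transcription factors of hypothalamic nuclei, NR5A1 was at 1.87 ± 0.95 (adjusted p = 0.73 by limma), ISL1 at 0.98 ± 0.75 and ARNT2 at -0.03 ± 0.20. OXT differed by -2.71 after BCO without estradiol and by 1.64 with it. Named genes with the lowest p were on the positive side AREG (1.95 ± 0.47), HCRTR1 (2.15-fold, SE 0.31 on the log2 scale), GAL, OXT and GRP. On the negative side they were AGGF1 (-0.74 ± 0.13), PRNP (-0.58 ± 0.12), KDR (-1.14 ± 0.25), FTO (-0.80 ± 0.18) and the chromatin protein gene PSIP1 (-0.89 ± 0.21), with the PRNP and KDR values from a dimmer probe and an adjusted p of 0.125 for AGGF1. By limma 1 of 12937 probes passed, with 933 at an unadjusted p under 0.05. It was again A_70_P055401 (-1.30 ± 0.18, adjusted p = 0.0476), and its group means were -1.78 ± 0.15 in control, -1.45 ± 0.21 in BCO, -1.19 ± 0.17 in estradiol and -2.16 ± 0.14 in estradiol+BCO fetuses (SD, n = 4 each), and -1.41 and -1.19 within slides. It passed in 8 of 27 alternative fits (adjusted p = 0.0176 to 0.952), and with slide as a block 3 probes passed (adjusted p = 0.0176 for this one). In fits that left out 1 array this probe passed in 3 of 16, and the number of probes was 3 without BCO replicate 1. It was 0 without each of the control replicates 1, 2, 3 and 4, BCO replicates 2 and 3, estradiol+BCO replicates 1, 2, 3 and 4, and estradiol replicates 1, 2 and 3. The number of lists was 4 without control replicate 1, 3 without estradiol replicate 3, and 2 without control replicate 4, BCO replicate 1, estradiol+BCO replicate 2 or estradiol replicate 1.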

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

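The explanations weighed in this part, the splits and the tests of dissection, leukocytes and array gaps were chosen after the result was seen, while values within slides and fits that left out 1 array were planned. Arrays were checked group by group for 1 array lying far from the other 3, by its gap to the nearest of them as a share of the group's range. Chance marks about 1 in 20 groups in this way, and 27 of 427 groups of named probes (6.32%) were marked. The shares were 0.859 for ATP6V1B2 (estradiol+BCO replicate 2), 0.918 for AVPR1B (estradiol replicate 1), 0.89 and 0.906 for CD247 (BCO replicate 4 and estradiol replicate 4), 0.905 for COL3A1 (estradiol replicate 2), 0.836 and 0.903 for DCN (BCO replicate 3 and control replicate 2), and 0.904 and 0.88 for ESR2 (control replicate 2 and estradiol replicate 1). They were 0.92 for FBLN1 (control replicate 2), 0.859 for FCER1G (estradiol+BCO replicate 1), 0.914 for GJA1 (estradiol+BCO replicate 4), 0.837 for GRM5 (estradiol replicate 3), 0.921 and 0.923 for ITGA4 (estradiol replicate 3 and estradiol+BCO replicate 4), 0.851 for ITGB2 (estradiol replicate 3), 0.862 for KIT (estradiol+BCO replicate 3) and 0.918 for MGLUR1 (control replicate 2). They were 0.89 for MGLUR3 (BCO replicate 2), 0.836 for NPVF (BCO replicate 1), 0.921 for PC1 (estradiol+BCO replicate 3), 0.865 for PTCH1 (control replicate 1), 0.965 for SLC15A1 (BCO replicate 4), 0.907 and 0.839 for SST (BCO replicate 4 and estradiol+BCO replicate 3), 0.859 for STAR (estradiol replicate 4) and 0.884 for TAC3 (estradiol replicate 2). NPVF on the array apart was at -1.65 against -4.58 to -4.10 on the other BCO arrays, and SST in BCO at 1.78 against 2.97 to 3.09. The median local background of estradiol replicate 1 was 65 units, a share of 0.90. A difference in the effect of BCO between estradiol-treated and untreated fetuses passed its test for the probe A_70_P055401 (interaction -1.30) and for the neuropeptide list (adjusted p = 0.000408, but adjusted p = 0.717 with an estimated correlation). A neuropeptide p as small as that of the interaction came up in 13 of 100 splits (lowest other 1.21e-12).

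The first pattern was the lower signal of neuropeptide genes after BCO. The list p was as small as the real 7.06e-12 in 1 of 35 splits of the same 8 arrays, the real one itself, and the lowest other was 5.61e-08. The other comparisons that called this list had as small a p in 3 of 35 splits (estradiol+BCO against BCO), 1 of 100 (averaged BCO) and 16 of 100 (averaged estradiol). Of the 35 splits, 18 place 2 arrays of each side on each slide, as the real one does, and these are too few for a share under 5%. The list was also singled out after its values were seen. Each slide held 2 arrays of every group, so a slide shift shared by the groups could not make this difference. The smaller of the within-slide medians was -1.37. It comes from the arrays over which the list was singled out, so it decides nothing further. A smaller share of mediobasal hypothalamus in the dissected BCO samples cannot be told apart from an effect of occlusion, since dissection was not measured. The mean of GHRH, AGRP, POMC, NPY and GAL shifted by -3.40 between BCO and control (-2.72 without GHRH). It ranged over 4.06 log2 units among 4 sham-occluded estradiol fetuses. That range lay between the slides, with 0.55 within slide 1 and 0.96 within slide 2, each from 2 fetuses. In control the slides differed the other way, with -0.82 and -0.56 on slide 1 and 0.16 and 0.53 on slide 2. A slide shift shared by the groups therefore does not account for the range among estradiol fetuses. In the groups compared the range was smaller than the shift, 1.36 in control and 0.97 in BCO. The mean of OXT, GNRH1 and NPVF, which are made in other nuclei, shifted by -2.63. Its range in BCO was larger, 3.58, and BCO replicate 1 (-2.19) lay above control replicate 4 (-2.32). NR5A1 of the ventromedial nucleus was lower in BCO by over 2 standard errors (-2.18 ± 0.67, SE), as less mediobasal tissue would give. This 1 gene does not single out that cause. POMC is also a member of the pituitary list, which was not called in any comparison. ISL1 differed by -1.24 ± 0.53 and ARNT2 by -0.05 ± 0.14. An effect of occlusion on transcription or RNA stability in these neurons was not tested apart from sampling, and both are hypotheses. Tissue was taken 1 h after the start of the occlusion. Such an effect would therefore have to give the shift of -3.40 within that time, and RNA decay was not measured.

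The second pattern was the higher signal of inflammation genes in estradiol+BCO than in control fetuses. The list p of 6.07e-07 was reached by 2 of 35 splits (lowest other 5.33e-07), so chance cannot be excluded at this number of splits. In estradiol+BCO against estradiol a p as small came up in 6 of 35 splits, and in estradiol+BCO against BCO in 8 of 35. For averaged BCO it was 9 of 100 and for averaged estradiol 4 of 100, so the first 3 of these calls are also within chance. In this comparison the list was called in 16 of 16 fits that left out 1 array, so this call did not rest on 1 array alone. It was weakest without estradiol+BCO replicate 1 (adjusted p = 0.00205 by camera). Without that array the inflammation call was lost in estradiol+BCO against estradiol (0.156), estradiol+BCO against BCO (0.0845) and averaged BCO (0.0547). It was kept for averaged estradiol (0.0303). More leukocytes or blood in the samples could also raise such genes and cannot be told apart, because the microglia and leukocyte list had a median of 0.18, with members in both directions, and beta globin HBB differed by 0.30 ± 0.82 (SE). The treatments themselves, the biological difference that the design names, stay open, and which cells the transcripts came from was not tested.

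The third pattern was A_70_P055401, lower in estradiol+BCO than in estradiol fetuses. Each slide held 2 arrays of every group, so a slide shift shared by the groups could not make this difference. The smaller within-slide fold change was -0.92. It comes from the arrays over which the probe was singled out, so it decides nothing further. A gap of 0.56 log2 units separated the lowest estradiol from the highest estradiol+BCO array. The probe was singled out for its difference, so such a gap was likely beforehand and cannot decide whether 1 array mattered. A count of at least 1 probe came up in 3 of 35 splits in this comparison (real count 1, highest other 1) and in 11 of 100 in the interaction (real count 1, highest other 2), so chance cannot be excluded for either count. With no gene name for the sequence no biological explanation was tested.

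For the other counts of probes the splits exclude nothing, since the real count was 0. For BCO against control 35 of 35 splits gave as many (highest other 3, from the split that follows the slides). With slide as a block the real grouping gave 0 there, and the other splits were not fitted in that way. As many came up in 35 of 35 for estradiol against control (highest other 0) and 35 of 35 for estradiol+BCO against BCO (highest other 9). The same held in 35 of 35 for estradiol+BCO against control (highest other 2). For the averaged effects 100 of 100 drawn splits gave as many, with a highest other of 157 for BCO, from a split with 7 of its 8 first-side arrays on slide 1, and of 142 for estradiol, from a split with 7 of 8 on slide 2. Slide was not a term of these fits, so such splits restate the slide difference, a structure of the samples. Probes at an unadjusted p under 0.05 made up 3.28% (estradiol against control) to 9.45% (estradiol+BCO against BCO), where 5% are expected by chance. As many came up in 9 of 35 splits for BCO against control, 3 of 35 for estradiol+BCO against estradiol and 6 of 35 for estradiol+BCO against BCO. The number of lists for estradiol+BCO against BCO (real 4, highest other 3) was reached by 1 of 35 splits, the smallest share among 8 comparisons, and 0 lists were called there with an estimated correlation. The 18 splits balanced over the slides are again too few for a share under 5%. For the averaged effects and the interaction the 100 splits were drawn without regard to slide, so their list counts also hold the slide difference. For the number of lists chance cannot be excluded for BCO against control (real 2, 9 of 35 splits, highest other 3), estradiol+BCO against estradiol (real 3, 6 of 35, highest other 5), estradiol against control (real 0, 35 of 35, highest other 4), estradiol+BCO against control (real 1, 27 of 35, highest other 4), BCO averaged over estradiol (real 4, 5 of 100, highest other 6), estradiol averaged over BCO (real 2, 33 of 100, highest other 4) or the interaction (real 1, 74 of 100, highest other 8).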

How the results depend on the processing

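All alternatives were planned. Over all settings there were 6720 alternative fits of 236 values of single probes. They moved beyond the spread of replicates in 125 fits, and the sign turned in 162 fits, which fell on 52 of the 236 values. The unnamed A_70_P055401 lost its call in 35. Called lists kept the call in 420 fits, lost it in 69 and turned in 3. Normexp background correction, whose offset compresses dim signals, lowered the fold changes of GHRH, SELP, AQP3, TNF and EPAS1 given beside their values. The median log2 fold change of all probes was farthest from 0 with normexp in estradiol+BCO against estradiol (-0.075, against -0.008). Signal over background limits what can be said of the 2071 probes not tested. The causes of the changes below were not tested, except that single slides hold fewer arrays. In BCO against control, probes numbered 14 within slide 2 and 3 with the groups compared alone, against 0, and lists 4 with normexp, 1 within slide 2, 0 with an estimated correlation and 1 by fry, against 2. In estradiol+BCO against estradiol, probes numbered 0 with median centring, within slide 1, within slide 2, with the replicate block, with the series matrix values and with the groups compared alone, against 1, and lists 1 with probes well above background on all 16 arrays, 1 within slide 2, 0 with an estimated correlation and 1 by fry, against 3. With the filter on all 16 arrays 17 lists were tested. The fibroblast list was not among them, and the axis list had an adjusted p of 0.103 by camera. In estradiol against control there were 3 lists within slide 1, 1 within slide 2 and 1 probe within slide 2, against 0. In estradiol+BCO against BCO there were 13 probes within slide 2, against 0, and 2 lists within slide 2, 0 with an estimated correlation and 0 by fry, against 4. In estradiol+BCO against control there were 3 probes within slide 2, against 0, and 5 lists with quantile normalization, 3 within slide 2, 0 with an estimated correlation and 0 by fry, against 1. For BCO averaged over estradiol lists numbered 2 within slide 2, 0 with an estimated correlation and 2 by fry, against 4. For estradiol averaged over BCO there was 1 probe within slide 1, against 0, and lists numbered 4 with normexp, 4 within slide 1, 1 within slide 2, 0 with an estimated correlation and 0 by fry, against 2. For the interaction probes numbered 0 with quantile normalization, median centring, no filter, slide 1, slide 2 and the series matrix values, and 3 with slide as a block and with the replicate block, against 1, and lists 4 with no filter, 2 within slide 1, 0 with an estimated correlation and 0 by fry, against 1. Within slide 2 the direction turned for inflammation in estradiol+BCO against BCO (adjusted p = 0.923), inflammation for averaged estradiol (0.935) and neuropeptides for averaged estradiol (0.286).

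Leaving out 1 array gave, for BCO against control, 0 to 6 probes (6 without BCO replicate 2) and 1 to 3 lists (1 without BCO replicate 1 or 2). It gave 0 to 1 probes and 0 to 4 lists for estradiol+BCO against estradiol (0 lists without estradiol+BCO replicate 1), 0 to 0 and 0 to 0 for estradiol against control, 0 to 5 and 2 to 5 for estradiol+BCO against BCO (5 probes without BCO replicate 1, 2 lists without BCO replicate 2), and 0 to 0 and 1 to 6 for estradiol+BCO against control (6 without control replicate 2). It gave 0 to 0 and 1 to 6 for averaged BCO (1 without estradiol+BCO replicate 1, 6 without control replicate 2), 0 to 1 and 1 to 5 for averaged estradiol (1 probe without estradiol replicate 4, 1 list without estradiol replicate 2) and 0 to 3 and 1 to 4 for the interaction (3 probes without BCO replicate 1, 4 lists without control replicate 1). The neuropeptide list was called in 16 of 16 such fits in BCO against control, estradiol+BCO against BCO, averaged BCO and the interaction, and the inflammation list in estradiol+BCO against control and averaged estradiol.

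Replicate numbers were checked for pairing of fetuses. Arrays of the same number in different groups had correlations across probes of -0.03 to 0.27 (mean 0.13), against a mean of 0.14 for other numbers on the same slide. Of 16 arrays 3 were closest to their own number. With the slide removed the range was -0.22 to 0.01, but removing group and slide means itself lowers these correlations, so that range cannot decide. By the other values no pairing by number was seen, and probes are not independent replicates. With the replicate block the counts were 0 probes for BCO against control and 0 for estradiol+BCO against estradiol.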

Other observations

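The test of sampling among the 5 arcuate genes was chosen after the result was seen. Lists not called in any comparison are given here by their lowest adjusted p over the 8 comparisons: 0.0686 for immediate early genes (estradiol+BCO against control), 0.145 for hypoxia targets (BCO averaged over estradiol), 0.494 for oxidative phosphorylation, 0.57 for prostaglandin synthesis and receptors, 0.614 for estrogen signalling, 0.136 for apoptosis, 0.209 for ribosomal proteins, 0.649 for the unfolded protein response, 0.419 for astrocytes, 0.135 for endothelial and mural cells and 0.0679 for the pituitary. All 8 measured hypoxia targets had higher mean signal after BCO than in control, with a median of 0.06 (adjusted p = 0.168). In the pituitary list, the glycoprotein hormone subunit CGA differed by -4.76 ± 2.15 (SE) between estradiol+BCO and estradiol fetuses and by -3.08 ± 2.15 between BCO and control, and prolactin (PRL) by 0.01 ± 1.04 and -2.26 ± 1.04. Among genes of lists too small to test, the choroid plexus gene TTR differed by -2.15 ± 1.12 between estradiol+BCO and control, -1.72 ± 1.12 between estradiol and control and -1.21 ± 1.12 between BCO and control. In the last of these beta globin HBB differed by 0.62 ± 0.82 and the chaperone gene HSP90AA1 by 0.02 ± 0.13.

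The mean of GHRH, AGRP, POMC, NPY and GAL, genes of the arcuate nucleus, was -0.17 ± 0.63 in control, -3.57 ± 0.42 in BCO, -0.68 ± 1.96 in estradiol and -1.93 ± 1.63 in estradiol+BCO fetuses (SD, n = 4 each). In the estradiol groups it followed the slide: estradiol fetuses had 0.70 and 1.25 on slide 1 and -1.84 and -2.81 on slide 2, and estradiol+BCO fetuses -1.22 and 0.03 on slide 1 and -3.46 and -3.07 on slide 2. The control arrays had -0.82 and -0.56 on slide 1 and 0.16 and 0.53 on slide 2. The mean of OXT, GNRH1 and NPVF was -1.30 ± 0.75 in control, -3.93 ± 1.65 in BCO, -1.83 ± 0.99 in estradiol and -1.05 ± 0.73 in estradiol+BCO fetuses (SD, n = 4 each). Its range in BCO was 3.58, and the BCO and control arrays overlapped.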
